A study of Mus musculus with 4 samples.

How the data were processed

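The series holds 4 RNA-seq libraries of mouse forebrain at E10.5, 2 control and 2 cKO. Per the labels' protocols, total RNA was extracted and polyA RNA libraries were made with a VAHTS Universal V8 kit. The submitters' processing notes name HISAT2, featureCounts and DESeq2 and the mm10 genome (the UCSC name of GRCm38); the versions of HISAT2 and DESeq2 are not given in the sources used here. The deposited count table holds raw read counts of paired-end reads over exons, summed per gene for 24982 genes, made with featureCounts 2.0.1 on a RefSeq annotation of mm10, per the file headers. The recorded command sets no strand option, so reads over exon bases shared by a gene and its antisense partner cannot be told apart. The authors also deposited a comparison table with log2 fold changes, standard errors, p-values and adjusted p-values, and with normalized counts; each normalized count (a signal scaled by the authors) equals the raw count divided by 1 constant per library, from 0.990 to 1.013. The table also holds a Wald statistic per gene, a score that the authors deposited and that was not used. Among its symbols, 26 are not symbols of the count table, having turned into dates. Its values were used only where the authors' deposited table is named. Samples were grouped by the genotype in the labels, and 0 columns of per-sample values were left without a sample.

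From the counts, genes were kept by filterByExpr (minimum count 10), which left 14235 genes; genes outside it took 0.0651% to 0.0679% of each library's counts. Library sizes were scaled by TMM. The cKO was compared with the control in edgeR 4.0.16 (glmQLFit and glmQLFTest, under R 4.3.3) with no covariate, and p-values were adjusted by Benjamini-Hochberg over all genes tested; adjusted p under 0.05 was called. The SE of a log2 fold change was taken as its size over the root of the F statistic. Total counts of 16581252 to 17096522 per library and a common biological coefficient of variation of 0.0785 set the precision. The most abundant gene, Eef1a1, took 0.827% to 0.942% of counts. The replicates of a group were checked as distinct libraries: the chi-square of their counts per degree of freedom was 5.53 for the controls and 4.66 for the cKO pair. Xist was at 1634 to 1920 CPM and the Y-linked genes had a summed count of 0 or 1 in each of the 4 libraries; the sex-linked list was described only.

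Before the data were examined, 31 gene lists, the rule for named genes and the alternatives were fixed. Of the list symbols, 16 were not matched, among them all 15 mitochondrially encoded genes, which the count table does not hold, and 0 were matched through a synonym. None of the 39 Hox genes passed the count filter. The other 28 lists were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset inter-gene correlation 0.01, two-sided, adjusted over lists), with camera using an estimated correlation, and with fry. The names given are Chd7 and Sox1; the 10 largest increases and decreases among called genes with a mean of at least 5 CPM whose cKO libraries lie on the same side of both controls, without predicted or sex-linked genes; up to 4 called members per list, or the 2 with the smallest p where none was called; and 13 genes chosen in advance. Some members with no call are given in the list counts only, and a few results under this rule are not reported here. Coordinates are from the RefSeq annotation of GRCm38.p6. Of 97 genes under this rule, exons of 32 overlap exons of another gene in GENCODE M21, 26 of them on the opposite strand.

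The edgeR step was tested on simulated counts for 14052 genes with 200 changed. The changed genes were drawn from those with a mean of at least 5 CPM. Every gene had the dispersion of the fitted trend, without a spread between genes of equal level. It recovered 70.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 10 false calls among 189. In the camera step a simulated list moved down was called down, and 4 of 200 unmoved lists had an unadjusted p under 0.05. The simulated genes were drawn independently of each other. This check therefore does not cover lists whose members vary together, such as the proneural list with an estimated correlation of 0.625.

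The alternatives were DESeq2 size factors, upper-quartile factors, no count filter, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, glmTreat against a 1.5-fold change, the replicate number as a block, each library left out in turn, and erythroid genes removed. A fit that leaves out a library assumes that the lone library of its group varies like those of the other group. Plots were drawn with matplotlib 3.10.9.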

Results

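RNA sequencing was performed on micro-dissected forebrain of mouse embryos at E10.5 (the embryonic day), when the telencephalic vesicles are growing and the earliest neurons are being formed. The question named by the title and design was how the chromatin remodeller CHD7 affects the expression of neurogenic genes. The 4 libraries fell into 2 groups of 2. The control libraries carried the genotype Chd7 +/f, with 1 floxed allele and no Cre in the label. The conditional knockout (cKO) libraries carried 2 floxed Chd7 alleles and Sox1-Cre, a Cre recombinase named for the Sox1 gene and active in the early neural tube. Because the Cre allele was named for the cKO libraries alone, an effect of that allele itself cannot be separated from that of Chd7 loss in any value below. The count table gave totals of 16609514 counts for control replicate 1, 16916602 for control replicate 2, 16581252 for cKO replicate 1 and 17096522 for cKO replicate 2. The labels do not say whether a library was made from 1 embryo or from a pool, so the p-values measure the spread between these libraries only. Levels below are in CPM, counts scaled to library size, as mean ± SD with n = 2 per group, and log2 fold changes are cKO over control with a standard error (SE).

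In the cKO forebrain Chd7 fell, as did 10 of 25 tested genes of the subpallium (the ventral telencephalon), 7 of 27 proneural and neurogenic genes and 9 of 32 neuronal genes, while 10 of 16 genes of the FGF pathway and 11 of 32 of the Wnt and BMP pathways rose. In the opposite direction, 1 subpallial gene rose and 3 Wnt and BMP pathway genes fell. Markers of other cell types moved in the same comparison: 8 of 14 erythroid genes were lower and 0 higher (median log2 fold change −0.67), and the endothelial list had a median of −0.25 with 0 of 20 genes called by edgeR. None of these 7 lists was called by the camera set test with an estimated inter-gene correlation (adjusted p = 0.441 to 0.612). The homeobox genes Dlx1, Dlx2 and Gsx2, which specify subpallial progenitors, were 11.8-fold, 8.48-fold and 7.27-fold lower. Without cKO replicate 1 the log2 fold change of Dlx1 went from −3.56 to −4.39 and that of Dlx2 from −3.08 to −4.06, and without cKO replicate 2 that of Dlx2 was −2.50. Fgf8, the signal of the anterior neural ridge, was 2.78-fold higher, and Bmp7, a roof plate signal, was 2.56-fold higher. Of 14235 genes tested, 223 were higher and 303 lower in the cKO at an adjusted p under 0.05 (edgeR quasi-likelihood test), and 51 of the former and 110 of the latter differed by more than 2-fold. The calls made up 3.70% of the genes tested. Leaving out a library moved the counts of higher and lower genes to 121 and 179 (control replicate 1), 351 and 418 (control replicate 2), 143 and 191 (cKO replicate 1) or 80 and 131 (cKO replicate 2).

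The targeted gene was lower in both cKO libraries. Chd7 (GRCm38 chromosome 4, 8690402 to 8868449), an ATP-dependent remodeller of the chromodomain helicase family, measured 342 ± 4.1 CPM in the control and 134 ± 2.9 CPM in the cKO forebrain, with a log2 fold change of −1.35 (SE 0.05, edgeR adjusted p = 8.7e-05). The cKO level was 39.1% of the control level. The counts cover all exons of the gene, and which exon is floxed is not given in the sources used here, so reads outside the deleted part are included, as are reads from any cells in which Cre was not active. Sox1 (chromosome 8, 12395519 to 12399555), a SoxB1 transcription factor of neural progenitors and by name the Cre carrier locus, was 175 ± 3.4 CPM in control and 143 ± 5.7 CPM in cKO libraries (log2 fold change −0.29, SE 0.05, adjusted p = 0.031). This call was lost when control replicate 1 (adjusted p = 0.099), cKO replicate 1 (0.137) or cKO replicate 2 (0.083) was left out. Chd8, a related remodeller, had a log2 fold change of −0.05 (SE 0.05, adjusted p = 0.63).

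The 10 largest decreases were led by Dlx6os1 (chromosome 6, 6820543 to 6871627), a long non-coding RNA of the Dlx5 and Dlx6 locus, which went from 13.6 ± 1.6 to 0.299 ± 0.088 CPM (log2 fold change −5.47, SE 0.30, adjusted p = 0.00051). Dlx1 (chromosome 2, 71528113 to 71533981) went from 16.3 ± 1.1 to 1.38 ± 0.86 CPM (−3.56, SE 0.33, adjusted p = 0.0031) and Dlx2 from 22.9 ± 0.56 to 2.70 ± 1.9 CPM (−3.08, SE 0.36, adjusted p = 0.0064). The exons of Dlx1 share 335 bases with the opposite-strand gene Dlx1as, and without strand information reads there count for neither gene with certainty. The ephrin receptor Epha5 fell by 3.16 on the log2 scale, Gsx2 by 2.86, the POU-domain factor Pou4f1 by 2.83, the dachshund family member Dach2 by 2.65, the zinc finger factor St18 by 2.35, the LIM-homeobox factor Lhx9 by 2.33 and the microtubule-associated protein gene Map7 by 2.25 (adjusted p 0.00067 to 0.0073). The 10 largest increases were Igsf21 (log2 fold change 1.89), the extracellular matrix gene Thbs4 (1.83), the zinc finger factor Glis3 (1.81), Tcerg1l (1.78), Megf11 (1.71), Sez6l (1.67), Disp3 (1.53), Fgf8 (1.47), Fam163a (1.46) and the netrin-G gene Ntng2 (1.46). Glis3 (chromosome 19, 28258851 to 28680265) was the most abundant of these, at 12.5 ± 0.63 CPM in control and 43.9 ± 2.5 CPM in cKO forebrain (SE 0.10, adjusted p = 0.00063). Without cKO replicate 1 the value of Dach2 was −3.33, and without control replicate 2 that of Fgf8 was 2.09. Leaving out a single library ended the calls of Disp3 (adjusted p = 0.072 without control replicate 1, 0.124 without cKO replicate 2), Ntng2 (0.078 and 0.147 for the same libraries), Fgf8 (0.114 without cKO replicate 1, 0.082 without cKO replicate 2) and Tcerg1l (0.052 without cKO replicate 2).

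**Figure D1:**
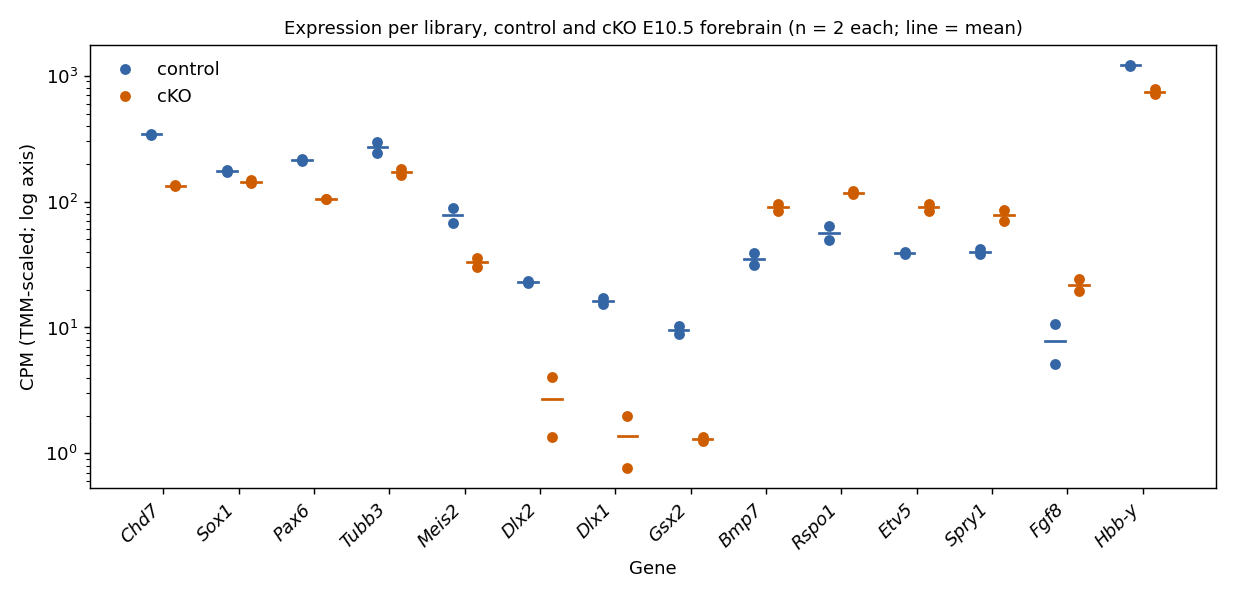
Expression of 14 genes in each library, as CPM on a log axis, for control (blue) and cKO (orange) forebrain; each point is a library and each bar a group mean (n = 2). Chd7 sat at 342 CPM in the control and 134 CPM in the cKO mean, Dlx1 at 16.3 and 1.38 CPM, and Fgf8 at 7.88 and 21.9 CPM.

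Of 25 tested members of the ventral telencephalon list, 10 were lower and 1 higher, and 15 lower and 2 higher when adjusted over the list alone; the median log2 fold change was −1.52. Besides Dlx1, Dlx2 and Gsx2, the decreases included Gad2, which encodes an enzyme of GABA synthesis (9.28 ± 1.1 to 0.480 ± 0.34 CPM, log2 fold change −4.26, SE 0.40, adjusted p = 0.0031; −5.25 without cKO replicate 1 and −3.67 without cKO replicate 2), and the homeobox gene Meis2 (77.7 ± 15 to 32.9 ± 4.1 CPM, −1.24, SE 0.14, adjusted p = 0.0062). The member that rose was the zinc finger gene Sp8 (log2 fold change 0.51, adjusted p = 0.042), singled out after its value was seen; no member was called higher without cKO replicate 1. The camera set test called the list lower (adjusted p = 9.2e-07), a call not kept with an estimated inter-gene correlation (adjusted p = 0.441). Without cKO replicate 2, 6 members were called lower, and without control replicate 2 the list median was −0.92. Markers of the most ventral tissue differed between libraries of the same group. Nkx2-1 counts were 57 and 577 in control replicates 1 and 2 and 71 and 136 in cKO replicates 1 and 2, and its log2 fold change of −1.60 (SE 0.85, adjusted p = 0.389) became 0.85 without control replicate 2 and −2.46 without control replicate 1 (adjusted p = 0.0042). Shh counts, in the same order, were 113, 387, 41 and 686.

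In the proneural and neurogenic list, 7 of 27 tested members were lower and 0 higher (17 and 0 when adjusted over the list alone), with a median log2 fold change of −0.57. St18 and Myt1, zinc finger factors of neuronal differentiation, and Scrt1, a transcriptional repressor of new neurons, were among them; Myt1 went from 43.0 ± 9.8 to 16 ± 1.9 CPM (−1.43, SE 0.17, adjusted p = 0.0070). The call of Scrt1 was lost without cKO replicate 2 (adjusted p = 0.052). The bHLH gene Neurod1 fell by 0.87 on the log2 scale (SE 0.16, adjusted p = 0.034), and its call was lost without control replicate 1 (adjusted p = 0.113), cKO replicate 1 (0.105) or cKO replicate 2 (0.093). Neurog2, a proneural factor, was at 64.7 ± 29 CPM in control and 26.9 ± 2.6 CPM in cKO libraries (log2 fold change −1.26, SE 0.27, adjusted p = 0.0504). Its value was −0.72 without control replicate 1 (adjusted p = 0.026) and −1.66 without control replicate 2 (8.0e-05). Neurog1 was at 23.3 ± 1.9 and 25.4 ± 2.4 CPM (0.12, SE 0.12, adjusted p = 0.66). Of 32 tested neuronal genes, 9 were lower and 0 higher (17 and 0 when adjusted over the list alone), with a median of −0.49. The neuronal tubulin gene Tubb3 went from 269.8 ± 36 to 171 ± 12 CPM (−0.66, SE 0.09, adjusted p = 0.013), the tau gene Mapt from 14.5 ± 2.6 to 5.04 ± 0.48 CPM (−1.52, SE 0.19, adjusted p = 0.0086) and the RNA-binding protein gene Elavl3 was 1.87-fold lower (−0.90, SE 0.11, adjusted p = 0.0078). Dcx, a microtubule protein of migrating neurons, was at 105 ± 34 and 65.2 ± 3.5 CPM (log2 fold change −0.68, SE 0.19, adjusted p = 0.106). Its value was −0.31 without control replicate 1 (adjusted p = 0.124) and −0.98 without control replicate 2 (0.00017). Both lists were called lower by camera (adjusted p = 1.4e-06 for proneural and 8.8e-08 for neuronal genes), and neither call was kept with an estimated correlation (adjusted p = 0.612 and 0.441). The counts of lower members rested on the libraries used. Without control replicate 1 they were 5 proneural and 9 neuronal genes, and without control replicate 2 they were 17 and 15, with 1 neuronal gene higher. Without cKO replicate 1 they were 4 and 6, and without cKO replicate 2 they were 3 and 7. The proneural median was −0.22 without control replicate 1. The proneural list took 0.119% of counts in control replicate 1, 0.0888% in control replicate 2, 0.0685% in cKO replicate 1 and 0.0723% in cKO replicate 2.

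Genes of the dorsal telencephalon moved in both directions, 7 of 25 higher and 7 lower (8 and 8 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.812). The median, −0.05, and the camera direction, up, differed in sign. Those that fell included Pax6, a homeobox factor of cortical progenitors (213 ± 7.2 to 105 ± 0.62 CPM, −1.03, SE 0.05, adjusted p = 0.00034) and the nuclear receptor gene Nr2f1 (−1.30, SE 0.09, adjusted p = 0.0011). Those that rose included Bmp7 (35.1 ± 5.3 to 89.9 ± 8.4 CPM, 1.36, SE 0.11, adjusted p = 0.0018) and Rspo1, which encodes an enhancer of Wnt signalling (56.7 ± 9.7 to 118 ± 3.8 CPM, 1.05, SE 0.10, adjusted p = 0.0037). Emx2, a dorsal homeobox gene, was at 154 ± 35 and 146 ± 11 CPM (−0.08, SE 0.13, adjusted p = 0.82).

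Of 16 tested members of the forebrain signalling centre list, 10 were higher and 0 lower (13 and 1 when adjusted over the list alone), and the median log2 fold change was 0.86. Fgf8 (chromosome 19, 45736491 to 45742941) measured 7.88 ± 3.8 CPM in control and 21.9 ± 3.2 CPM in cKO libraries (1.47, SE 0.29, adjusted p = 0.042); its call was lost without cKO replicate 1 or cKO replicate 2, as given above. The FGF-induced transcription factor gene Etv5 went from 38.9 ± 1.1 to 90.2 ± 8.4 CPM (1.22, SE 0.08, adjusted p = 0.00086). Spry1 (0.96, SE 0.11), Il17rd (0.76, SE 0.10) and Dusp6 (0.70, SE 0.11), feedback inhibitors of FGF and ERK signalling, had adjusted p of 0.0059, 0.0092 and 0.018. Camera called the list higher (adjusted p = 7.4e-08), and not with an estimated correlation (adjusted p = 0.441). Without a library, between 4 (cKO replicate 1 left out) and 9 members (cKO replicate 2 left out) were called, with 6 and 7 in the fits without control replicates 1 and 2.

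The Wnt and BMP pathway list had 11 of 32 members higher and 3 lower (17 and 5 when adjusted over the list alone), with a median of 0.42. Axin2, a feedback target of Wnt signalling, rose from 129.8 ± 4.1 to 186 ± 4.6 CPM (0.52, SE 0.05, adjusted p = 0.0037), and Tcf7, a Wnt-pathway transcription factor, from 26.2 ± 0.19 to 46.8 ± 2.3 CPM (0.83, SE 0.08, adjusted p = 0.0038). The BMP-responsive gene Id3 rose by 0.60 (SE 0.08, edgeR adjusted p = 0.0094). Id4, of the same family and list, fell from 306 ± 76 to 110 ± 23 CPM (−1.48, SE 0.18, edgeR adjusted p = 0.0078). It was named after its value was seen. The ligand gene Wnt7a fell by 1.40 (SE 0.15, adjusted p = 0.0044). The list was called higher by camera (adjusted p = 1.0e-05), and not with an estimated correlation (adjusted p = 0.441). Without cKO replicate 1, 5 members were lower. In the midbrain and hindbrain list 1 of 10 members was higher and 0 lower (5 and 0 when adjusted over the list alone; median 1.06, camera adjusted p = 0.0015, 0.441 with an estimated correlation). That member was Cnpy1, a Canopy family gene (1.46 ± 0.15 to 5.86 ± 1.0 CPM, 4.01-fold, SE 0.29 on the log2 scale, adjusted p = 0.013), whose call was lost without cKO replicate 1 (adjusted p = 0.074). Without control replicate 2, 4 members were higher, and without cKO replicate 2 the list median was 0.68.

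Of 18 diencephalon genes, 4 were lower and 0 higher (4 and 4 when adjusted over the list alone); they included Tcf7l2 (149 ± 9.5 to 60.5 ± 1.4 CPM, −1.30, SE 0.06, adjusted p = 0.00034), Lhx9 and Foxb1 (−1.56, SE 0.19, adjusted p = 0.0073). The list was not called (camera adjusted p = 0.625), and its median, 0.12, and the camera direction, down, differed in sign. Without control replicate 2 or cKO replicate 1, 4 members were higher. Among axon guidance genes 8 of 38 were lower and 2 higher (10 and 3 when adjusted over the list alone; median −0.19, camera adjusted p = 0.0302, 0.441 with an estimated correlation). Robo2, a Slit receptor, fell from 33.9 ± 3.2 to 8.21 ± 0.019 CPM (−2.05, SE 0.13, adjusted p = 0.00075) and the ephrin receptor Epha3 from 135 ± 31 to 33.8 ± 7.7 CPM (3.99-fold, SE 0.19 on the log2 scale, adjusted p = 0.0031). The increases were the netrin receptors Unc5b (0.52) and Unc5c (0.48), named after their values were seen. The camera call of this list was lost in the fits without control replicate 2 (adjusted p = 0.094), cKO replicate 1 (0.0525) and cKO replicate 2 (0.097). Its median was −0.0946 without control replicate 1, −0.12 without control replicate 2 and −0.11 without cKO replicate 2. The counts lower and higher were 6 and 1 without control replicate 1, 8 and 5 without control replicate 2, 5 and 3 without cKO replicate 1 and 4 and 0 without cKO replicate 2.

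Of 22 neural progenitor genes, 7 were lower and 2 higher (12 and 4 when adjusted over the list alone; median −0.22, camera adjusted p = 0.0302, 0.612 with an estimated correlation). The camera call was lost without control replicate 1 (adjusted p = 0.089) or cKO replicate 1 (0.119). The counts lower and higher were 10 and 4 without control replicate 2 and 4 and 1 without cKO replicate 2. Pax6, the SoxB1 gene Sox3 (108 ± 14 to 55.2 ± 2.0 CPM, −0.97, SE 0.09, adjusted p = 0.0035) and the chromatin protein gene Hmga2 (−0.52, SE 0.06, adjusted p = 0.0055) fell. Sox2 was at 372 ± 34 and 351 ± 32 CPM (−0.09, SE 0.08, adjusted p = 0.66). In the Notch list 3 of 24 genes were lower and 1 higher (8 and 3 when adjusted over the list alone): the receptors Notch1 (−0.51) and Notch3 (−0.26) and the feedback gene Nrarp (−0.36) fell, and Notch2 (0.35) rose, with adjusted p of 0.015 to 0.037. The list was not called (camera adjusted p = 0.126), and each of the 4 calls was lost without cKO replicate 1 or without cKO replicate 2 (adjusted p 0.052 to 0.161); that of Notch3 was also lost without control replicate 1 (0.110) or control replicate 2 (0.051). The Notch counts lower and higher were 2 and 1 without control replicate 1, 5 and 1 without control replicate 2, 0 and 0 without cKO replicate 1 and 1 and 0 without cKO replicate 2. Of 45 cell cycle genes 2 were higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.527). They were the D-type cyclin genes Ccnd2 (0.59, adjusted p = 0.032) and Ccnd1 (0.22, adjusted p = 0.041); the call of Ccnd2 was lost without control replicate 1 (adjusted p = 0.078), its value being 0.38 without cKO replicate 2, and that of Ccnd1 without any of the 4 libraries (0.071 to 0.176).

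Of 14 tested erythroid (red blood cell) genes 8 were lower and 0 higher (10 and 0 when adjusted over the list alone), with a median of −0.67 and a camera adjusted p of 2.3e-09 (0.441 with an estimated correlation). The embryonic globin genes Hbb-y (1209 ± 14 to 745 ± 52 CPM, −0.70, SE 0.05, adjusted p = 0.0014), Hbb-bh1 (−0.67, SE 0.06) and Hba-x (−0.65, SE 0.06) and the erythrocyte anion exchanger gene Slc4a1 (−0.69, SE 0.07) fell. Globin genes are close copies of each other, so the division of reads among them is uncertain. The erythroid list took 0.335% ± 0.017 of counts in control and 0.217% ± 0.0066 in cKO libraries (SD, n = 2). In the fits that left out a library, 5 to 7 erythroid genes were called lower, with 5 in the fits without control replicate 1 and without cKO replicate 2. In the lists for other non-neural cells edgeR called 0 of 20 endothelial genes (median −0.25, camera adjusted p = 0.00026, 0.441 with an estimated correlation), 0 of 16 myeloid genes (−0.45, 0.0039, 0.612) and 1 lower of 21 mesenchyme genes (−0.27, 0.0321, 0.814), the forkhead gene Foxd1 (−0.86, SE 0.12, adjusted p = 0.013). At an unadjusted p under 0.05 there were 9 endothelial and 2 myeloid genes, and 0 of either were called by the DESeq2 Wald test or limma-voom. Adjusted over the list alone, 3, 0 and 5 were lower and 0 higher. The call of Foxd1 was lost without cKO replicate 2 (adjusted p = 0.064), and the camera call of the mesenchyme list without control replicate 2 (0.574) or cKO replicate 2 (0.547). The mesenchyme median was −0.41 without control replicate 1, −0.0385 without control replicate 2, −0.54 without cKO replicate 1 and 0.0211 without cKO replicate 2, with 1, 2, 7 and 0 genes lower in that order. The myeloid median was −0.23 without cKO replicate 2. Of 16 surface ectoderm genes edgeR called 0, with 1 at an unadjusted p under 0.05 and 1 higher when adjusted over the list alone. That gene, Epcam, which encodes an epithelial adhesion molecule, had a log2 fold change of 1.11 (SE 0.24, adjusted p = 0.052). It was called higher by the DESeq2 Wald test (adjusted p = 0.0021), by limma-voom (0.045), with no count filter (0.0496) and without control replicate 2 (0.0027). In the authors' deposited table Epcam was at 1.11 with an adjusted p of 0.0020. The surface ectoderm list had a median of 0.17 and a camera adjusted p of 0.0382 (0.814 with an estimated correlation). The median became −0.49 without control replicate 1, 2.38 without control replicate 2, −0.13 without cKO replicate 1 and 0.70 without cKO replicate 2, with 1, 6, 0 and 0 genes called higher in that order.

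Of 25 hypoxia and glycolysis genes 2 were higher and 0 lower, and 17 higher when adjusted over the list alone (median 0.27, camera adjusted p = 1.0e-05, 0.612 with an estimated correlation). They were Slc2a1, a glucose transporter gene (231 ± 24 to 341 ± 39.8 CPM, 0.56, SE 0.09, adjusted p = 0.023), and Ddit4, an inhibitor of mTORC1 (0.55, SE 0.10, adjusted p = 0.030). Both calls were lost without control replicate 1 (adjusted p = 0.054 and 0.068) or cKO replicate 2 (0.080 and 0.083), where the list median was 0.18. In those 2 fits 0 members were called, but 6 were higher without control replicate 2 and 14 without cKO replicate 1. The DESeq2 Wald test called 11 of these genes higher.

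The remaining lists were not called by camera. Of 17 neural crest genes 1 was lower, the endothelin receptor gene Ednrb (−1.36, SE 0.14, adjusted p = 0.0044; camera adjusted p = 0.532), and camera called this list without control replicate 1 (adjusted p = 0.0137) or cKO replicate 1 (0.033), where 2 and 3 members were lower. Without control replicate 2, 1 neural crest gene was higher. Of 10 eye field, retina and lens genes 1 was higher, the transcription factor gene Maf (0.81, SE 0.12, adjusted p = 0.016; camera adjusted p = 0.081); the call of Maf was lost without cKO replicate 1 (adjusted p = 0.062), and the list was called without control replicate 2 (0.0275) or cKO replicate 2 (0.038). Without control replicate 2, 4 of its members were higher, and without control replicate 1 there was 1 lower. Of 34 chromatin remodeller genes 1 was higher, Smarca2, an ATPase of the BAF complex (0.56, SE 0.07, adjusted p = 0.0082; camera adjusted p = 0.677), and 3 were lower without control replicate 2. Of 20 immediate early and heat shock genes 1 was lower, Jun (−0.35, SE 0.06, adjusted p = 0.031; camera adjusted p = 0.929), and its call was lost without control replicate 1 (0.072), cKO replicate 1 (0.059) or cKO replicate 2 (0.186); 2 members were lower without control replicate 2. By edgeR 0 genes were called among 30 p53 targets (camera adjusted p = 0.201), 15 Hedgehog pathway genes (0.625), 39 Polycomb and Trithorax genes (0.676), 22 ER stress genes (0.201), 22 cholesterol synthesis genes (0.297) and 11 histone genes (0.848). At an unadjusted p under 0.05 these lists held 5, 5, 4, 8, 3 and 0 genes in the same order. The DESeq2 Wald test called 2 p53 targets (1 higher, 1 lower) and 3 Hedgehog pathway genes (1 higher, 2 lower), and limma-voom called 0. In the fits without a library edgeR called 1 p53 target higher without control replicate 1, and 1 higher and 1 lower without control replicate 2. It called 3 Hedgehog pathway genes lower without control replicate 1, 1 lower without control replicate 2 and 1 higher without cKO replicate 2. It called 1 ER stress gene higher without control replicate 2. Adjusted over the list alone, these 6 lists had calls in the Hedgehog list, with 3 lower and 1 higher; the counts were 1 lower for neural crest, 3 higher and 1 lower for eye, 1 higher for chromatin remodellers and 2 lower for immediate early and heat shock genes. Cdkn1a, a p53 target that arrests the cell cycle, was at 9.62 ± 3.3 and 15.4 ± 0.33 CPM (0.68, SE 0.22, adjusted p = 0.175), and without control replicate 1 its log2 fold change was 1.07 (adjusted p = 0.031). Without control replicate 2 it was 0.37 (0.338).

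**Figure D2:**
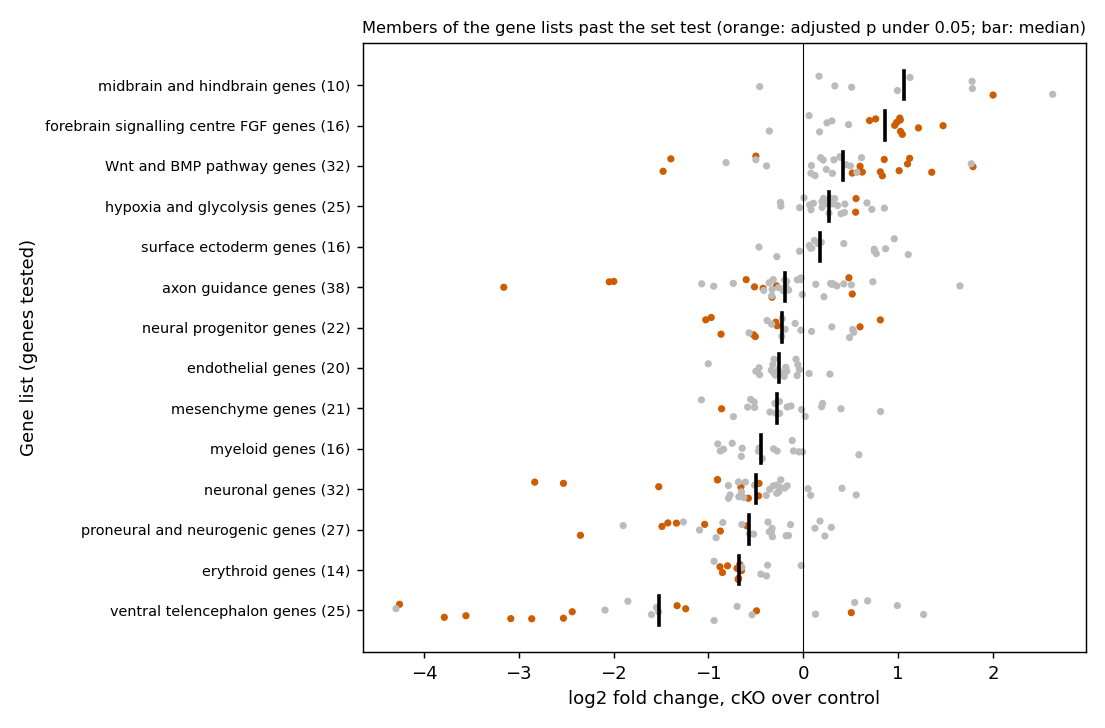
Log2 fold changes (cKO over control) of the tested members of the 14 gene lists called by camera; each point is a gene, orange where its edgeR adjusted p is under 0.05, and each black bar is the list median. The ventral telencephalon median lies at −1.52, the erythroid median at −0.67 and the FGF median at 0.86.

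In all, camera with a preset correlation called 14 of 28 lists, 5 higher and 9 lower. With an estimated correlation 0 were called (1 at an unadjusted p under 0.05), and the directional fry test called 0 (smallest adjusted p = 0.062, 8 at an unadjusted p under 0.05). The mixed fry test, which asks whether members change in either direction, called 16 of the 28. All 526 called genes had non-overlapping groups, as did 48.3% of all genes tested, where chance gives 33.3% for 2 libraries against 2. A single-gene exact permutation test of this size cannot give a two-sided p below 0.333.

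The authors' deposited table of the same comparison held 626 genes at an adjusted p under 0.05, 278 higher and 348 lower. Of these, 469 were also called by edgeR in the same direction, 0 in the opposite direction, and 157 were called in the authors' deposited table alone; 57 were called by edgeR alone. Both come from the same libraries, so the overlap describes the tools.

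**Figure D3:**
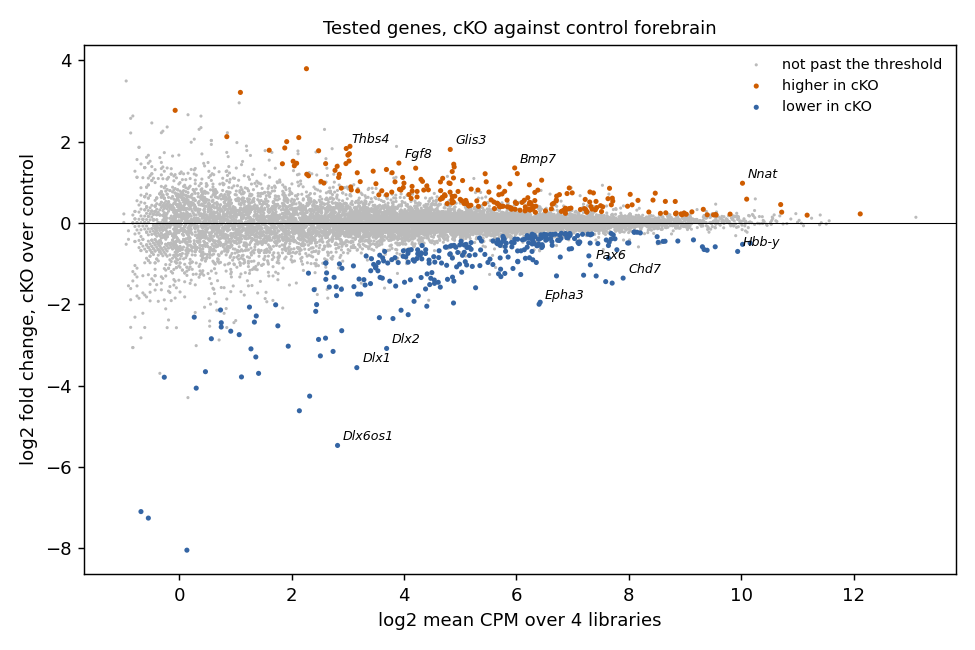
Log2 fold change (cKO over control) against log2 mean CPM over the 4 libraries for the 14235 genes tested; orange points are the 223 genes higher and blue points the 303 genes lower in the cKO at an adjusted p under 0.05, grey points the rest. Chd7 lies at −1.35 and Dlx6os1 at −5.47.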

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

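The test for less ventral tissue and the test for an earlier stage were set before their results were seen; the others in this part were chosen only after the result was seen. So was the requirement that a whole bootstrap interval, not the median alone, pass the bound set for an explanation, and the median of ventral markers with Lhx8. By the median alone, the test for less ventral tissue would have counted against that explanation. The test for midbrain-hindbrain boundary tissue would have counted for its explanation.

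Genes under the count filter, outside the comparison, were searched for counts above the control level. Gm20052 had 15 counts over the cKO libraries and 0 in the controls, and D930020B18Rik had 18 against 1. Both were picked by this search, made in 1 direction only, so by themselves they show no difference between the groups.

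The first pattern is the lower level of subpallial and neuronal genes in the cKO. A single library as the whole cause is argued against, because in each of the 4 fits without a library at least 6 ventral, 3 proneural and 6 neuronal genes were called lower and at most 1 of a list higher, where the share called among all genes gives at most 0.914 genes (largest adjusted p = 0.0017, one-sided Fisher's exact test over genes, which are not independent). The size of the change did rest on single libraries, since the proneural median went from −0.57 to −0.22 without control replicate 1 and the ventral median from −1.52 to −0.92 without control replicate 2. Less ventral tissue in the cKO dissection remains open. The 7 ventral midline and hypothalamic markers had a median of 0.13 (95% bootstrap interval over genes −1.52 to 1.27). With Lhx8, at a mean of 0.989 CPM just under the minimum of 1 CPM, the median of 8 was −0.41 (−1.60 to 1.27). All of these markers but Foxa2 were also members of the ventral telencephalon list. The test therefore drew on genes of the pattern itself and cannot decide the question. An earlier stage of the cKO embryos may also contribute. The 8 early embryonic timing genes had a median of 0.0753 (interval −0.03 to 0.52), and 37.5% of them had negative values. Trim71 was highest at 0.69 (edgeR adjusted p = 0.174), followed by Lin28a at 0.52. Hmga2 was lowest at −0.52 and was the only member called (edgeR adjusted p = 0.0055). The genotype, Chd7 loss together with the Cre allele, stays open as an untested explanation.

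The next pattern is the higher level of FGF pathway genes. A single library as the whole cause is argued against, because in each of the 4 fits without a library at least 4 of its 16 genes were called higher and 0 lower, where the share among all genes gives at most 0.384 genes (largest adjusted p = 1.7e-05, the same test). Midbrain-hindbrain boundary tissue in the cKO dissection could be a source, as 6 boundary markers had a median of 1.38. The 95% bootstrap interval of −0.06 to 2.21 and mean levels of 1.19 to 4.89 CPM leave it open. Pax5 was at −0.46, and edgeR called none of the 6 markers (adjusted p 0.085 to 0.771). Wnt1 varied between the cKO libraries (6.50 ± 5.3 CPM). The midbrain and hindbrain list, which shares markers with these, had a median of 1.06 and 1 call, Cnpy1, as given above. The engrailed genes of that region had few counts in every library. En1 had 0 and 7 counts in control replicates 1 and 2, and 0 and 2 in cKO replicates 1 and 2. En2 had 1, 1, 4 and 10 counts in the same order, and Fgf8 had 86, 180, 402 and 332. Thus En2 was higher in both cKO libraries and En1 was not, at counts too low to decide the question. An effect of the genotype in the forebrain itself remains open and was not tested separately.

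The last pattern is the lower level of erythroid genes, where all 14 tested members had negative values. A single library as the whole cause is argued against, because in each of the 4 fits without a library at least 5 were called lower and 0 higher, where the share among all genes gives at most 0.400 genes (largest adjusted p = 6.3e-07, the same test). Fewer blood cells in the cKO tissue may account for it but remains open. The SD of the 14 log2 fold changes was 0.244 (95% bootstrap interval 0.126 to 0.329). It includes the sampling error of each gene, so it cannot decide whether all members fell by 1 amount. The 4 members with the smallest p fell by similar amounts, Hbb-y by 0.70 (SE 0.05), Hbb-bh1 by 0.67 (SE 0.06), Hba-x by 0.65 (SE 0.06) and Slc4a1 by 0.69 (SE 0.07). Because they were picked by p, their likeness cannot show that all 14 fell by 1 amount. The division of reads among the globin genes is also uncertain, and edgeR did not call 6 of the 14. Epb42, an erythroid gene outside the list, was 2.01-fold lower (edgeR adjusted p = 0.037). A smaller share of all non-neural tissue also remains open. Over the 4 fits without a library the endothelial, myeloid and mesenchyme medians lay 0.16 to 0.66 above the erythroid median. The surface ectoderm and neural crest lists were not part of this comparison, and their medians were 0.17 and −0.02. Positive values were held by 13 of 16 and 8 of 17 members. Without single libraries these medians ranged from −0.49 to 2.38 and from −0.21 to 0.19, so they do not settle the question. The vascular genes Aplnr (−0.66, edgeR adjusted p = 0.0078) and Cd34 (−0.48, adjusted p = 0.0092) were lower. Both are outside the lists and were picked after their values were seen. Whether blood in the embryos or blood left in the dissected tissue differed was not tested, and neither was the genotype as an explanation.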

How the results depend on the processing

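All alternatives here were planned. The 223 higher and 303 lower genes stayed within 1.5 times those counts under DESeq2 size factors, upper-quartile factors, no count filter, a mean of at least 5 CPM, limma-voom, the DESeq2 Wald test and removal of erythroid genes (206 to 275 higher, 271 to 349 lower), and no called gene reversed in any alternative. Against a 1.5-fold change glmTreat called 13 higher and 48 lower, 61 shared with the authors' calls, and Sox1 at −0.29 was lost (adjusted p = 1); the stricter null is the cause by construction. Without a library the counts ranged from 80 to 351 higher and 131 to 418 lower, and calls shared with the authors from 200 to 506; the gene counts were 121 and 179 without control replicate 1, 351 and 418 without control replicate 2, 143 and 191 without cKO replicate 1 and 80 and 131 without cKO replicate 2. Sox1 ranged from −0.33 to −0.25 without a library. The number of changed lists went from 14 to 0 with an estimated correlation and to 0 with directional fry. Correlated members alone do not account for the former. The estimated correlation of axon guidance genes was −0.019, under the preset 0.01, yet their unadjusted camera p went from 0.013 to 0.101. That of neuronal genes was 0.028, and their unadjusted camera p went from 9.5e-09 to 0.041. The cause was not tested for either.

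With the replicate number as a block, 137 genes were higher and 211 lower, and Sox1 was at −0.29 (adjusted p = 0.065). Among list counts, FGF genes went from 10 to 5 higher, diencephalon genes from 0 to 2, hypoxia and glycolysis genes from 2 to 5, p53 targets from 0 to 1, cell cycle and axon guidance genes from 2 to 1 higher, mesenchyme genes from 1 to 2 lower and immediate early and heat shock genes from 1 to 0 lower; counts of other lists stayed within 1.5 times. Nothing in the labels says that equal numbers mark a litter or day, and the deviations of same-numbered libraries correlated at −0.053 across genes.

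Chd7 and Sox1 were left out of the counts that follow, and the lost calls of Sox1 are given above. Of 1223 values of the 95 other named genes under alternatives, 1115 kept their direction and side of the threshold. The call was lost in 85 and gained in 19, and 4 reversed. Another 12 could not be computed because the setting left out the gene or gave it no adjusted p. Those that reversed were uncalled in all libraries, and without a library Sox2 ranged from −0.18 to 0.012, its other reversal being 0.0062 without cKO replicate 1, Emx2 from −0.29 to 0.17 and Nkx2-1 from −2.46 to 0.85, the ends of Nkx2-1 being the fits without control replicate 1 (adjusted p = 0.0042) and 2.

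Of 360 list values, 299 kept direction and side, 41 lost the call, 4 gained it and 16 reversed the direction of the set test. List medians for those reversals were 0.27 for diencephalon genes without a count filter, 0.0021 for immediate early and heat shock genes at a mean of 5 CPM and −0.0514 for dorsal telencephalon genes with fry; under the block they were 0.11 for diencephalon genes and −0.00935 for dorsal telencephalon genes. Without a library the medians ranged from −0.15 to 0.17 for dorsal telencephalon genes, −0.40 to 0.41 for diencephalon genes, −0.0168 to 0.0360 for cell cycle S and G2/M genes, −0.27 to 0.0845 for Hedgehog pathway genes, −0.0638 to −0.0231 for chromatin remodeller genes, −0.21 to 0.19 for neural crest genes, −0.49 to 2.38 for surface ectoderm genes, −0.0714 to 0.12 for immediate early and heat shock genes and −0.19 to −0.000944 for replication-dependent histone genes. The cause was not tested. With 2 libraries per group, leaving out any of them removes 1 of 2 residual degrees of freedom. At the present depth and size, simulated 1.5-fold changes were recovered in 70.1% of changed genes, all with a mean of at least 5 CPM. That simulation held no spread of dispersion between genes of equal level.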

Other observations

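The tests in this part were chosen only after the results were seen, and no explanation is offered.

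The genes in this paragraph were picked after their values were seen. Among POU-domain factors of neural progenitors, Pou3f4 went from 46.3 ± 0.89 to 22.7 ± 3.3 CPM (log2 fold change −1.03, SE 0.11, adjusted p = 0.0049), Pou3f3 fell by 0.64 (SE 0.08, adjusted p = 0.0084) and Pou3f2 by 0.63 (SE 0.12, adjusted p = 0.040), while Pou3f1 was at 0.69 (SE 0.31, adjusted p = 0.317). The orphan nuclear receptor gene Nr2e1, which maintains progenitors, went from 199 ± 28 to 113 ± 10.1 CPM (−0.81, SE 0.10, adjusted p = 0.0081), Dach1 from 141 ± 14 to 78.8 ± 9.8 CPM (−0.84, SE 0.10, adjusted p = 0.0070) and Sox21 from 72.4 ± 4.7 to 48.3 ± 1.2 CPM (−0.59, SE 0.07, adjusted p = 0.0078). Slc32a1, the vesicular GABA transporter gene, fell from 2.41 ± 0.49 to 0.330 ± 0.22 CPM (−2.85, SE 0.53, adjusted p = 0.035), and Th, the tyrosine hydroxylase gene, from 4.13 ± 0.35 to 0.476 ± 0.25 CPM (−3.09, SE 0.42, adjusted p = 0.011).

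The imprinted gene Nnat, a neuronatin gene of the early nervous system, went from 698 ± 21 to 1377 ± 24 CPM (log2 fold change 0.98, SE 0.04, adjusted p = 0.00023). Of 30 imprinted genes, 4 were higher and 2 lower; Nnat, Mest (0.45, adjusted p = 0.0156), Ndn (0.46, adjusted p = 0.0167) and Blcap (0.34, adjusted p = 0.032) rose, and Plagl1 (−0.47, adjusted p = 0.0237) and Peg10 (−0.45, adjusted p = 0.042) fell. The median of the list was −0.02, at percentile 16.6 of 10000 random lists of equal size matched on mean expression.

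Of 79 ribosomal protein genes, 15 were higher and 0 lower, and 77 had a positive log2 fold change. The median, 0.16, lay above that of all 10000 matched random lists, and was 0.16 with DESeq2 size factors and 0.17 with upper-quartile factors. Random lists do not allow for correlation among the members, so this rank is not a test of a difference between the groups. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain.

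Within 10 Mb of Chd7, 3 of 51 tested genes were called (5.88%: Chd7, Tox and Rps20), and within 10 Mb of Sox1 3 of 77 (3.90%: Sox1, Irs2 and Atp11a), beside 3.70% of all genes tested. The median genomic length was 46.6 kb for genes lower in the cKO, 31.8 kb for genes higher and 23.8 kb for all genes tested.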
